A study of Homo sapiens with 4 samples.

How the data were processed

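Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in HAP1 cells, a near-haploid human cell line derived from a chronic myeloid leukaemia line. Antibodies were directed against CTCF, a zinc finger protein that binds DNA at insulators and loop anchors, and against SCC1 (also called RAD21), the kleisin subunit of the cohesin ring. Each antibody was used in wild-type cells and in a line whose CTCF carries the substitutions Y226A and F228A, so that 4 libraries were available, with 1 library per antibody and genotype. Per the labels' protocols, the substitutions were introduced with Cas9 and a repair oligonucleotide of 120 bases, cells were fixed in 1% formaldehyde and chromatin was sheared to 400 to 800 bp. The labels name an SCC1 antibody for the cohesin samples, whereas the extraction protocol names SMC1, another subunit of the same ring, and the labels' antibody is followed here.

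Per the submitters' processing notes, reads were trimmed with Trim Galore, peaks were called with MACS2 and coordinates are on hg19. The aligner, the call settings and any input control are not given in the sources used here. Each deposited list holds the peaks of a single library, so peaks were not called on pooled samples, and each entry has 1 summit. The fold enrichment is the authors' ratio of summit signal to the local background of that library. The −log10 p and −log10 q values are the authors' peak caller output for that library alone. The deposited score is the −log10 q multiplied by 10 and cut to a whole number, and was not used. These values were used as given only to describe, rank or filter peaks within their own list. The names of the peak entries begin with the same number in both SCC1 lists and with another in both CTCF lists, and what this number marks is not given. Those of both CTCF lists also carry a 2, while the labels give replicate 1, and whether another replicate exists is not known.

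The lists give no read totals. MACS2 writes fold enrichment as (pileup + 1) / (background + 1) and a Poisson p-value for that pileup, and both were solved for the number of fragments covering the summit and the expected background. The Poisson tail was continued to real numbers, so whole results were not built in. Solved summit counts lay within 0.01 of a whole number in 100% of the peaks of both SCC1 lists, and in all but 1 of the wild-type and 5 of the mutant CTCF peaks. Simulated whole counts were returned as whole in 100% of 5000 peaks, and simulated counts that were not whole in 0%. The lowest background of a list is the genome-wide value, which is proportional to depth times the fragment length used by the caller. That length is not given in the sources used here and can differ between libraries. The value is thus only a proxy for depth, and depth below means this value. The genome-wide background was 3.27 fragments for wild-type and 3.14 for mutant SCC1, and 3.50 for wild-type and 3.38 for mutant CTCF. The mutant libraries thus had 0.959 (SCC1) and 0.966 (CTCF) of the wild-type background. Ratios of solved summit counts between genotypes were scaled by this background, and redraws of counts at the depth of the other library used it too. A difference in fragment length would move all scaled ratios of an antibody by the same factor, so a scaled ratio of 1 need not mean no change. A redrawn peak counted as called when its −log10 p reached the 1% quantile of the −log10 p values of the other list.

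Peaks on chromosomes 1 to 22 and X were used. Entries with identical intervals were to be merged, but 0 were found in any list. A peak was called kept or shared when it overlapped a peak of the other list by at least 1 bp. A shared CTCF site is a wild-type CTCF peak that overlaps a mutant CTCF peak. SCC1 peaks away from CTCF overlap no CTCF peak of either genotype. Shares are given with 95% Wilson intervals. These cover counting error over peaks only, and neighbouring peaks are not independent. With 1 library per antibody and genotype no difference between genotypes has a replicate check, and no p-value is given. Chance overlap was measured by shifting 1 list 100 times along each chromosome, by at least 1 Mb. Strength was matched by deciles of the authors' fold enrichment within the wild-type SCC1 list, using deciles with at least 20 peaks of either class. Positions are hg19 and counted from 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, and the overlap rules were tested on simulated intervals against bedtools 2.31.1, from which they differed by 0 peaks.

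The designs and alternatives were fixed before the data were examined, apart from those named as later additions. The planned comparison of promoters, CTCF motifs and gene lists needed an hg19 annotation or sequence. The reference used here is a gene table of GRCh38, so these parts were not analysed here and no gene is assigned to a peak. By the rule fixed for that case, the 5 peaks with the highest fold enrichment per class are named by position. Alternatives were a stricter threshold, lists cut to equal length, all chromosomes, other overlap rules and other CTCF reference lists.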

Results

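CTCF and SCC1 occupancy was mapped by ChIP-seq in wild-type HAP1 cells and in HAP1 cells with CTCF Y226A and F228A. These residues lie in the N-terminal part of CTCF that contacts the cohesin subunits SA2 and SCC1. The comparison asks whether the mutant protein still occupies its sites and whether cohesin is still found there. The wild-type lists held 70595 CTCF and 51931 SCC1 peaks on chromosomes 1 to 22 and X, and the mutant lists 82575 and 47412. Median peak width was 352 bp (wild type) and 345 bp (mutant) for CTCF, and 592 bp and 508 bp for SCC1. The median number of fragments at the summit was 69 and 62 for CTCF, and 34 and 26 for SCC1. There was 1 library per antibody and genotype, so every value below is a single library's value.

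Most wild-type CTCF sites were called again in the mutant. Of the 70595 wild-type CTCF peaks, 93.2% (95% Wilson interval 93.0 to 93.4%) overlapped a mutant CTCF peak, against a mean of 2.06% and a maximum of 2.24% for shifted peaks. The share was higher among stronger peaks of the wild-type list, from 74.4% in the decile of lowest fold enrichment to 99.9% in the highest. It ranged from 88.5% on chromosome 13 to 96.5% on chromosome 19. In the other direction, 79.4% (79.1 to 79.7%) of mutant CTCF peaks overlapped a wild-type peak. The 16997 mutant-only peaks lay mainly among the weaker calls: 27.2% of the lowest decile of the mutant list was found in wild type, against 99.99% of the highest.

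**Figure D1:**
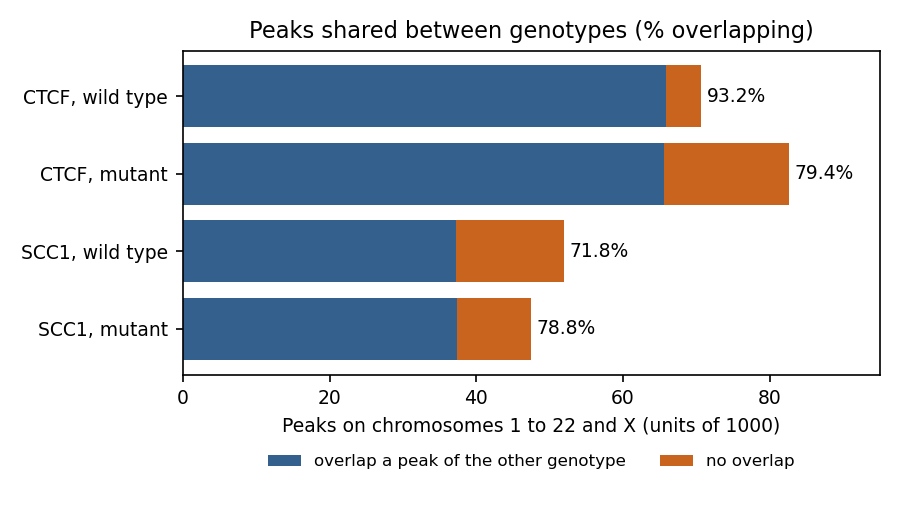
Number of peaks (horizontal axis, in units of 1000) in the 4 lists, split by whether they overlap a peak of the other genotype by at least 1 bp. The printed percentage is the overlapping share, which was 93.2% for wild-type CTCF and 71.8% for wild-type SCC1.

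A few strong CTCF peaks were called in a single genotype. The wild-type-only CTCF peaks of highest fold enrichment lay on chromosome 6 at 163602186 to 163602584 (25.4-fold) and 64722129 to 64722516 (24.5-fold), on X at 29108944 to 29109381 (24.3-fold), on chromosome 10 at 37552227 to 37552751 (23.9-fold) and on chromosome 9 at 137977890 to 137978246 (23.5-fold). Each of these 5 overlapped an SCC1 peak in wild type and none in the mutant. The strongest mutant-only CTCF peaks lay on chromosome 3 at 13068741 to 13069158 (25.6-fold), chromosome 2 at 173091087 to 173091456 (23.1-fold), chromosome 8 at 88121240 to 88121691 (22.1-fold), chromosome 19 at 4495533 to 4495917 (21.7-fold) and chromosome 6 at 7813977 to 7814339 (20.3-fold). Of these, the chromosome 2 peak overlapped SCC1 peaks in both genotypes, and the other 4 overlapped none in either.

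SCC1 peaks were kept less often than CTCF peaks. Of the 51931 wild-type SCC1 peaks, 71.8% (71.4 to 72.2%) overlapped a mutant SCC1 peak, against 1.81% for shifted peaks. Conversely, 78.8% (78.4 to 79.2%) of mutant SCC1 peaks overlapped a wild-type peak. Retention was 65.1% in the lowest decile of wild-type fold enrichment, 60.9% in decile 5 and 96.1% in the highest. By chromosome it ranged from 66.6% (chromosome 19) to 73.6% (chromosome 11). SCC1 peaks called in the mutant alone differed from the others in their relation to CTCF: 21.3% (20.5 to 22.1%) of the 10057 mutant-only SCC1 peaks overlapped a CTCF peak of either genotype, against 78.0% of the mutant peaks found in wild type, 78.0% of the wild-type peaks kept in the mutant and 80.5% (79.9 to 81.1%) of the 14659 wild-type-only SCC1 peaks. These shares were not matched for strength. In the mutant SCC1 list, 31.9% of the lowest decile of fold enrichment and 99.5% of the highest overlapped a mutant CTCF peak. Of the lowest decile 45.7% was found in wild type.

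The wild-type-only SCC1 peaks of highest fold enrichment all lay at shared CTCF sites. They were on chromosome 5 at 38809712 to 38810411 (15.2-fold, 136 fragments at the summit), chromosome 17 at 43462814 to 43463392 (14.6-fold), chromosome 2 at 27472851 to 27473541 (14.6-fold) and chromosome 1 at 13370592 to 13371332 (14.4-fold) and 13106342 to 13106996 (14.3-fold). Mutant-only SCC1 peaks were weaker within their list. The strongest were on chromosome 9 at 78789906 to 78790412 (9.08-fold) and 135457316 to 135457821 (7.84-fold), chromosome 13 at 114031061 to 114031770 (7.81-fold), chromosome 11 at 29549146 to 29549558 (7.49-fold) and chromosome 2 at 234608370 to 234609209 (7.33-fold). The stronger of the chromosome 9 peaks and the chromosome 11 peak overlapped CTCF in both genotypes, the other chromosome 9 peak overlapped CTCF in the mutant alone, and the remaining pair overlapped none.

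SCC1 was found at fewer CTCF sites in the mutant. At the same 65804 shared CTCF sites, 58.1% (57.7 to 58.4%) overlapped an SCC1 peak in wild type and 44.6% (44.2 to 45.0%) in the mutant, against 1.70% and 1.46% for shifted sites. Of these sites, 27694 had SCC1 in both genotypes, 10510 in wild type alone, 1651 in the mutant alone and 25949 in neither. The share was lower in the mutant on 23 of 23 chromosomes, with a mutant to wild-type ratio from 0.683 (chromosome 19) to 0.790 (chromosome 11). The gap depended on CTCF strength. In the decile of lowest wild-type CTCF fold enrichment the shares were 21.7% in wild type and 22.9% in the mutant, with overlapping intervals. In decile 6 they were 70.1% (69.0 to 71.2%) and 43.2% (42.0 to 44.4%), and in the highest decile 99.0% and 90.4%. The mutant SCC1 library had 0.959 of the wild-type genome-wide background.

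Seen from SCC1, the share of peaks at CTCF was also lower in the mutant. In wild type 75.4% (75.02 to 75.8%) of SCC1 peaks overlapped a CTCF peak, and in the mutant 65.4% (65.0 to 65.9%) did, against 2.28% and 2.55% for shifted peaks. SCC1 peaks without CTCF in either genotype numbered 11057 in wild type and 16146 in the mutant, of which 51.0% (50.2 to 51.8%) were found in the wild-type list. Within the wild-type SCC1 list, peaks at shared CTCF sites had a median fold enrichment of 7.33 (quartiles 4.93 and 10.1) and peaks away from CTCF 3.72 (3.30 and 4.21), a ratio of 1.97. Within the mutant list the medians were 5.40 (4.27 and 7.08) and 3.84 (3.38 and 4.45), a ratio of 1.41. The median summit count was 47 fragments at shared CTCF sites and 21 away from CTCF in wild type, and 30 and 21 in the mutant. The median width of peaks away from CTCF was 462 bp and 463 bp, while at shared CTCF sites it was 624 bp and 519 bp.

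SCC1 peaks at CTCF sites were kept less often than SCC1 peaks of like strength away from CTCF. Without regard to strength the classes were close, at 72.9% (72.4 to 73.3%) of 37644 peaks at shared CTCF sites and 74.2% (73.3 to 74.97%) of 11057 peaks away from CTCF. Within deciles of fold enrichment the share was lower at CTCF in each of the 7 deciles that held at least 20 peaks of either class. In decile 3 it was 49.2% (47.1 to 51.2%) at CTCF and 75.3% (73.5 to 77.0%) away, and in decile 5 it was 56.2% (54.6 to 57.7%) and 89.9% (87.7 to 91.7%). With these deciles weighted equally, 58.1% were kept at shared CTCF sites and 81.8% away from CTCF. The other overlap rules turned the direction of the unmatched difference: it was 1.29 percentage points in favour of peaks away from CTCF with 1 bp of overlap and -15.2 when summits had to lie within 200 bp. The matched difference was 23.7 percentage points with 1 bp and 10.6 with the summit rule, an alternative added after the data were seen.

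**Figure D2:**
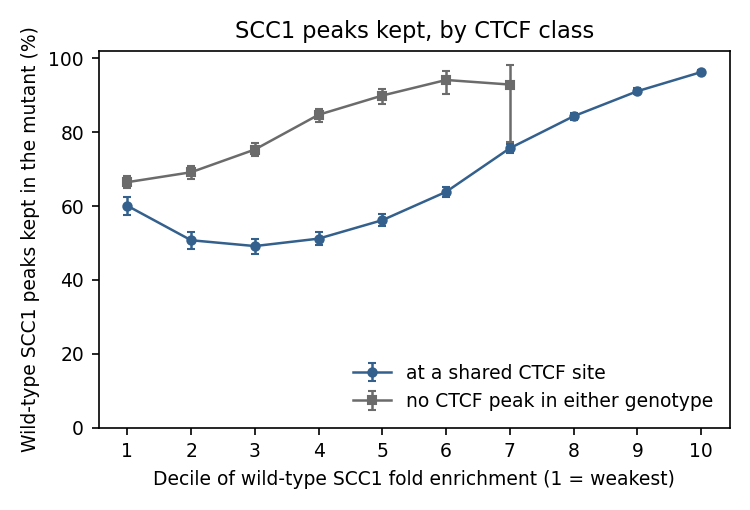
Share of wild-type SCC1 peaks that overlap a mutant SCC1 peak (vertical axis, percent) by decile of wild-type SCC1 fold enrichment (horizontal axis), for peaks at shared CTCF sites and peaks with no CTCF in either genotype, with 95% Wilson intervals. Only points with at least 20 peaks are drawn, and peaks away from CTCF lie above those at CTCF in each of the 7 deciles that have both.

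CTCF peaks called in a single genotype differed in SCC1. Of the 440 wild-type-only CTCF peaks with a fold enrichment of at least 10, 94.8% (92.3 to 96.5%) overlapped SCC1 in wild type and 0.682% (0.232 to 1.99%) in the mutant. Shared CTCF sites with a fold enrichment of at least 10 overlapped SCC1 in 84.2% in wild type. They included stronger peaks, as 16088 of these 37223 were 20-fold or more, against 25 of the 440. Between 10-fold and 15-fold, wild-type SCC1 was found at 93.0% of wild-type-only and 62.4% of shared wild-type CTCF peaks. Of the 158 mutant-only CTCF peaks with a fold enrichment of at least 10, 3.80% (1.75 to 8.04%) overlapped SCC1 in the mutant and 4.43% (2.16 to 8.86%) in wild type. Mutant peaks with a fold enrichment of at least 10 that were also called in wild type overlapped mutant SCC1 in 58.7% (58.2 to 59.2%). Between 10-fold and 15-fold, mutant SCC1 was found at 2.99% of mutant-only and 32.1% of shared mutant CTCF peaks. Over all strengths, SCC1 of the same genotype was found at 32.4% of the 4791 wild-type-only CTCF peaks and at 13.8% of the 16997 mutant-only ones. Wild-type SCC1 peaks at a wild-type-only CTCF peak were kept in the mutant in 13.2% (11.6 to 14.998%) of 1508 cases.

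**Figure D3:**
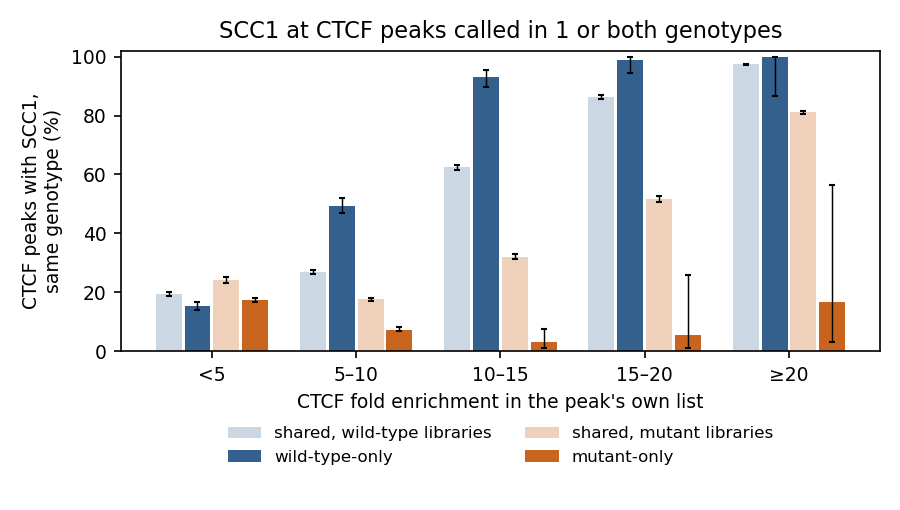
Share of CTCF peaks that overlap an SCC1 peak of the same genotype (vertical axis, percent) by fold enrichment of the CTCF peak in its own list (horizontal axis), for peaks shared between genotypes and peaks called in a single genotype, with 95% Wilson intervals. Between 10-fold and 15-fold, 93.0% of wild-type-only and 2.99% of mutant-only CTCF peaks had SCC1.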

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

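The numbers of peaks moved in opposite directions for the antibodies: the mutant list held 0.913 times as many SCC1 peaks as the wild-type list and 1.17 times as many CTCF peaks. This difference between antibodies was not tested, as each ratio rests on 1 library per genotype.

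Peaks also lay outside chromosomes 1 to 22 and X, which the main comparisons did not use. There were 419 in wild-type and 298 in mutant SCC1, and 1305 in wild-type and 1434 in mutant CTCF. On the alternate haplotype contigs of hg19 there were 159 and 41 SCC1 peaks, and 736 and 859 CTCF peaks. These contigs are alternative versions of regions of the main chromosomes, and how reads that match both were placed is not known. Using all chromosomes gave SCC1 at 57.6% of shared CTCF sites in wild type and 44.2% in the mutant.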

How the results depend on the processing

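The alternatives that matched peak strength by summit count, matched it under another overlap rule, or left out high backgrounds were chosen after seeing the data. No paired analysis was possible because each antibody and genotype has 1 library. The promoter, motif and gene list alternatives were not run, as no hg19 annotation was used here. Counting every deposited entry moved nothing, since no interval occurs more than once. SCC1 lay at more shared CTCF sites in wild type than in the mutant in 9 of 9 settings, SCC1 peaks lay at CTCF more often in wild type in 11 of 11, and wild-type CTCF peaks were kept more often than SCC1 peaks in 9 of 9. These tallies, like that of 13 settings below, include the main setting and the identical count of every deposited entry. They also count summits within 200 bp and 200 bp windows about the summits separately, although these rules are nearly the same. The number of shared CTCF sites with SCC1 in wild type alone ranged from 8559 to 11605, and in the mutant alone from 1335 to 2131. The difference in SCC1 retention between peaks away from CTCF and at shared CTCF sites was above 0 in 10 of 13 settings and reversed, without matching of strength, in the other 3, which all required closer overlap. Depth limits the weakest calls: the lowest 5% of the peaks of each list rested on at most 15 to 17 summit fragments.

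With a −log10 q of at least 5, 93.7% of wild-type CTCF peaks were kept and 80.3% of mutant CTCF peaks found in wild type, 66.8% of wild-type SCC1 peaks were kept and 80.8% of mutant SCC1 peaks found in wild type. SCC1 peaks were at CTCF in 82.6% (wild type) and 71.9% (mutant), and shared CTCF sites had SCC1 in 56.2% and 39.97%. Wild-type SCC1 peaks were kept in 67.6% at shared CTCF sites and 72.4% away from CTCF, 4.80 percentage points apart. With lists cut to equal length these values were 88.9% and 88.6% for CTCF, 73.2% and 73.8% for SCC1, 80.3% and 61.5% for SCC1 peaks at CTCF, 45.8% for shared CTCF sites with SCC1 in the mutant, and 73.9% and 81.1% for SCC1 kept at and away from CTCF, 7.12 points apart. With all chromosomes, shared CTCF sites had SCC1 in 57.6% (wild type) and 44.2% (mutant).

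With an overlap of at least 50% of the narrower peak, 70.3% of wild-type SCC1 peaks were kept and 76.96% of mutant ones found, 74.7% and 63.8% were at CTCF, shared CTCF sites had SCC1 in 57.4% and 43.7%, and 72.4% were kept at CTCF and 69.6% away, a reversed difference of -2.75 points. With summits within 200 bp, 92.4% of wild-type CTCF peaks were kept and 79.0% of mutant ones found, 63.6% of wild-type SCC1 peaks were kept and 69.6% of mutant ones found, 72.8% and 59.98% of SCC1 peaks were at CTCF, shared CTCF sites had SCC1 in 55.5% and 41.3%, and 69.3% were kept at CTCF and 54.2% away, a reversed difference of -15.2 points. Windows of 200 bp about the summits gave, in the same order, 92.4% and 79.0% for CTCF, 63.5% and 69.5% for SCC1, 72.8% and 59.9% for SCC1 at CTCF, 55.5% and 41.3% for shared CTCF sites with SCC1, and 69.3% at CTCF and 54.0% away for SCC1 kept, reversed at -15.3 points. The cause of these reversals was not tested. SCC1 peaks lay at the union of the CTCF lists in 78.7% (wild type) and 65.9% (mutant), and at their intersection in 72.5% and 61.1%.

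With peaks over 3 times the genome-wide background left out, 82.1% of wild-type CTCF peaks were kept and 75.2% of mutant ones found, 68.8% of wild-type SCC1 peaks were kept and 70.4% of mutant ones found, 63.0% and 41.3% of SCC1 peaks were at CTCF, shared CTCF sites had SCC1 in 46.98% and 34.0%, and 63.8% of SCC1 peaks were kept at CTCF, 10.7 points below those away. This filter was applied to each list separately, so a site left out of a single list counted as not shared. It also left out strong peaks, among them 20.3% of kept wild-type CTCF peaks of fold 10 or more. The lower shares are therefore not a measure of high background alone. Matched on deciles of fold enrichment, 58.1% of SCC1 peaks were kept at CTCF and 81.8% away, 23.7 points apart, and matched on summit count 58.6% and 84.4%, 25.9 points apart. Matched on fold, the rule of 50% of the narrower peak gave 56.2% and 79.1%, 22.9 points apart, and the summit rule 52.8% and 63.4%, 10.6 points apart.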

Other observations

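All tests of explanations below were written down before their values were computed, except that on the 2 cell clones, and the patterns themselves and some related values were seen first. The CTCF count ratios over all shared sites and at those without SCC1 in either genotype, all comparisons within deciles of CTCF fold, the matched redraw, the SCC1 ratios over all peaks, the runs of CTCF peaks and the summit distances at sites of equal count were added after the data were seen. Summit counts and summit distances were compared only at peaks or sites whose paired summits lay within 500 bp, so their numbers are slightly below those of all overlapping peaks.

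The background solved from the peak values was raised along a stretch of chromosome 15 in every library. Over the 6 regions of 5 Mb between 60 and 90 Mb (hg19), the median background was 9.24 fragments in wild-type SCC1 and 7.79 in mutant SCC1, and 8.62 and 7.85 in wild-type and mutant CTCF. Elsewhere in the genome the median regions had 5.27, 4.52, 4.97 and 4.68 fragments, so the ratios were 1.75, 1.72, 1.73 and 1.68. HAP1 cells are known to carry an additional copy of part of chromosome 15, and the raised stretch was present in both genotypes.

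At shared CTCF sites, the CTCF summit count in the mutant, scaled to the genome-wide background, was a median of 1.24 times that in wild type. The ratio was 1.43 at 25920 sites without SCC1 in either genotype, 1.17 at 27609 sites with SCC1 in both and 1.15 at 10489 sites with SCC1 in wild type alone. It was higher without SCC1 than with SCC1 in both in 10 of 10 deciles of wild-type CTCF fold enrichment, for instance 1.44 and 1.23 in decile 6. No biological explanation of this difference was tested.

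SCC1 peaks at shared CTCF sites were kept less often than peaks of like fold away from CTCF. Redrawing the wild-type summit counts from Poisson distributions at the mutant depth would keep 97.2% of the peaks at shared CTCF sites, against the observed 72.9%, which argues against depth and counting noise as the whole cause. Away from CTCF it would keep 81.8%, against the observed 74.2%, so it overstated retention there too, by less. With the 7 deciles of fold weighted equally, it would keep 92.0% at shared CTCF sites and 89.9% away, against the observed 58.1% and 81.8%. In the upper 5 deciles of fold enrichment the redraw kept 100.0% and 82.6% were observed. A lower pull-down efficiency at all sites would lower SCC1 counts away from CTCF too, provided that the peaks there are cohesin signal. Among peaks called in both genotypes, the depth-scaled mutant to wild-type ratio of SCC1 summit counts had a median of 1.19 (quartiles 0.999 and 1.41) at 7894 peaks away from CTCF. It was 0.562 (0.403 and 0.815) at 27139 peaks at shared CTCF sites. This test left out peaks not called in the mutant, and peaks away from CTCF lay close to the lowest counts called. With every wild-type peak included and those without a mutant partner within 500 bp ranked lowest, the median was 1.04 at 11057 peaks away from CTCF and 0.436 at 37644 peaks at shared CTCF sites. Among peaks with 40 to 49 wild-type summit fragments, of which 93.5% away from CTCF and 73.5% at CTCF had a partner, it was 1.07 and 0.522. SCC1 counts thus did not fall alike at all called peaks. Whether peaks away from CTCF are cohesin signal was not checked, and no input control is known, so a lower efficiency stays open. Weaker CTCF binding as the sole difference between sites that lost SCC1 and sites that kept it is argued against. The CTCF count ratio at sites with SCC1 in wild type alone was 0.981 times that at sites that kept it. For this quotient 0.8 or more had been set beforehand. The sites with SCC1 in wild type alone were weaker in CTCF, with a median wild-type fold of 14.2 against 19.9. Within deciles of CTCF fold their ratio was the lower in 9 of 10, with quotients from 0.873 (95% bootstrap interval 0.817 to 0.922, decile 3) to 1.03 (decile 1), so CTCF counts rose less at sites that lost SCC1. Their median ratio stayed above 1 in all 10 deciles, from 1.08 (decile 10) to 1.42 (decile 1). A ratio of 1 does not mark unchanged CTCF, as the median was 1.24 over all shared sites. At sites without SCC1 in either genotype it was 1.43, and only sites with CTCF called in both genotypes entered. Weaker CTCF relative to sites without SCC1 therefore stays open, both for sites that lost and for sites that kept SCC1. The spread was wider at sites that lost SCC1, with quartiles of 0.869 and 1.36, against 1.08 and 1.31 at sites that kept it. Scaled CTCF counts were thus below wild type at a part of the sites that lost SCC1. The hypothesis that the substitutions lower SCC1 at CTCF sites stays open, and so do a less efficient SCC1 pull-down and any other difference between the 2 cell lines. There was 1 library per antibody and genotype, so these cannot be told apart.

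Strong CTCF peaks called in wild type alone carried SCC1 there, and strong mutant-only peaks did not in the mutant. Depth and counting noise are argued against, since 100% of these peaks, of either genotype, would be called in a redraw at the other library's depth. Peaks of this strength lie far above the call threshold, so their selection all but fixed this result. The redraw also took the observed count as the true mean. Variation between libraries beyond counting noise is not covered by this redraw. Deletions in the mutant line stay open for the wild-type-only peaks. Of those of fold 10 or more, 77.95% (73.8 to 81.6%) had both neighbouring CTCF peaks called in the mutant, beside 88.2% for kept peaks, and the lower bound falls short of the 75% set beforehand. A deletion at these peaks would have to be narrower than the spacing of peaks, while at the others it could reach a neighbour. The longest run of wild-type-only CTCF peaks with a peak of that strength held 4 peaks. The longest of all, chosen for their length, held 9 weaker peaks (3.33-fold to 5.34-fold) on chromosome 13 from 57713311 to 57746271 and 6 (3.29-fold to 5.29-fold) on chromosome 5 from 49451694 to 49521240, and a deletion there was not tested. Sequence or methylation differences between the lines were not analysed here. High-background regions cannot be judged from the local background, since a fold of 10 or more is a ratio to it and disfavours high values. Of the strong peaks called in a single genotype, 2.68% had a local background over 3 times the genome-wide value. The share was 20.3% for kept wild-type CTCF peaks of fold 10 or more. Those were not matched for strength, so the gap between the shares is not read further. A candidate explanation is that CTCF binding at some sites depends on the presence of cohesin, which these lists cannot test.

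SCC1 summits lay a median of 27 bp (quartiles 13 and 46) from the CTCF summit in wild type and 31 bp (14 and 62) in the mutant at 26968 shared sites with SCC1 in both. Less precise summits at lower counts are a candidate cause that stays undecided. Within 7 bins of SCC1 summit count from 15 to below 100 fragments the mutant minus wild-type difference averaged -6.86 bp, with a range of -22 to 1 bp, but each library was binned by its own count, so a bin held different sites in the genotypes. At 2947 sites with both counts in the same bin the difference averaged 5.79 bp, with a range of -1 to 12 bp, and was above 0 in 6 of the 7 bins. Sites with 100 or more fragments, 6046 in wild type and 394 in the mutant, were left out of the bins. Strand of the CTCF motif was not analysed here.

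Whether the SCC1 sites absent from the mutant formed runs along the chromosome was also tested. Neighbouring wild-type SCC1 peaks at shared CTCF sites had the same fate in 61.6% of 37621 pairs, against a mean of 60.6% and a maximum of 61.1% in 100 permutations within fold deciles. The share lay above every permutation, but the excess stayed below the 2 percentage points set beforehand for a regional pattern. This average over the genome does not exclude loss in single regions. The longest run of consecutive SCC1 peaks absent from the mutant held 18 peaks, on chromosome 6 from 29720814 to 33091978, a region that alternate contigs of hg19 repeat. The next longest held 15 peaks, on chromosome 13 from 103600188 to 107173449. Both were chosen for their length, and their cause was not tested.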
